A study of Mus musculus with 11 samples.

How the data were processed

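The series profiled chromatin of Beko cells, a mouse pre-T cell line, by chromatin immunoprecipitation and sequencing (ChIP-seq). Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled after 24 h with DMSO, with apicidin at 0.01 mg/ml or with DAPT at 10 mg/ml, the doses as labelled. Apicidin is a histone deacetylase inhibitor that the labels describe as an HDAC3 inhibitor, and DAPT is a gamma-secretase inhibitor (GSI) that blocks the cleavage that activates Notch receptors. RBPJ, the DNA-binding protein through which cleaved Notch acts, was profiled in the DMSO cells. Of the 11 libraries, 2 were made for H3K27ac under each of the 3 conditions, 2 for RBPJ, and 1 input for each condition. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

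Reads were processed by the authors before deposition. The submitters' processing notes name FastQC, Bowtie2, SAMtools and deepTools, without versions, and the mouse build mm9, which is the build taken for all coordinates. The region caller, the read counter, the libraries on which regions were called and any use of the inputs are not given in the sources used here. The material used was the authors' deposited table of 56342 H3K27ac regions, which holds no value per library. Per the file headers, its columns are those that DESeq2 writes for each treatment, and the version is not given in the sources used here. The base mean is a signal that the authors computed as a mean of normalised read counts, and it was identical in both comparisons for all 56342 regions. The log2 fold changes and their standard errors (SE) are the authors' own, deposited for apicidin and for GSI. The headers name the treatment but not the reference, which was taken to be DMSO, the only control in the labels. The deposited Wald score equalled the fold change divided by its SE within 0.175%. The p-values and adjusted p-values are the authors' too, and Benjamini-Hochberg adjustment of the deposited p-values gave the deposited adjusted ones within 5.40e-07 for apicidin and 1.03e-06 for GSI. All regions had an adjusted p for apicidin, whereas 25756 had one for GSI and 30586 did not, the split lying at a base mean of 72.1. Regions without an adjusted p were kept as untested. The table further gives, by the authors, a gene symbol, the distance to its transcription start site (TSS, 0 where the region covers it) and a mark for overlap with an RBPJ site. The minimum overlap behind that mark is not given in the sources used here.

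Sequencing depth per library is unknown, because the table gives only fold changes and a mean over libraries. The precision that the libraries gave is carried by the SE, whose median fell from 0.572 in the lowest decile of base mean to 0.0917 in the highest for apicidin, and from 0.611 to 0.0940 for GSI. Changes at weakly acetylated regions are therefore the least certain.

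A region was counted as higher or lower where the authors' adjusted p was under 0.05. The planned direct contrast of both treatments needs values per library, so it was replaced by the difference of both log2 fold changes divided by the square root of the sum of their squared SEs, with a two-sided normal p and Benjamini-Hochberg adjustment over all 56342 regions. Both comparisons use the same DMSO libraries, so this SE is an upper bound. Overlap between the comparisons was set beside the overlap of independent lists and beside 100 simulated pairs of unchanged groups that share controls, with noise drawn from the deposited SEs. The controls could not be split, since the values of single libraries were not used here. RBPJ-overlapping regions were compared with 10000 random sets of other regions matched on 10 bins of base mean and on covering a TSS, giving a two-sided permutation p with a smallest possible value of 0.0002 and Benjamini-Hochberg adjustment over 18 tests.

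Gene lists (22 lists, 420 genes) were fixed, with the rule for named genes, the tests and most alternatives, before the data were examined. They cover Notch/RBPJ targets, Notch pathway and RBPJ cofactors, the HDAC/NCoR complex, histone acetyltransferases and bromodomain proteins, T-lineage identity, markers of B-lineage, myeloid, erythroid and megakaryocyte, natural killer and innate lymphoid, neuronal, and fibroblast and epithelial cells, cell-cycle inhibitors and p53 targets, cell-cycle genes, ribosomal proteins, housekeeping genes, heat shock and unfolded protein genes, NF-kB and cytokine genes, interferon response, apoptosis, replication-dependent histones, replication-independent and linker histone variants, and cholesterol and lipid synthesis. Each gene entered a list count with its region of highest base mean, and the list median was ranked among 10000 random gene lists of the same size matched on base mean, a permutation test adjusted over 44 tests. Counts are given over all regions tested and adjusted over the list alone. The named genes are, per comparison, the 10 largest increases and 10 largest decreases among called regions at or above the median base mean of the tested regions (61.3 for apicidin, 250 for GSI), 1 region per gene, with 13 fixed genes and up to 4 members of every list with the smallest p. For a gene with several regions the values are those of the region with the smallest p, which can differ from the region used in the list count. The table has 12081 symbols, of which 11219 matched a current symbol of assembly GRCm38.p6, 812 only a synonym and 50 neither. No coordinate was taken from that assembly. The 27 regions whose symbols had turned into calendar dates (7 symbols) were left out of naming. Some genes that the rule names are not reported here.

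The alternatives were other thresholds (adjusted p under 0.01 and under 0.1, an absolute log2 fold change of at least 1, Bonferroni adjustment), a filter at the median base mean, adjustment over all regions with a p-value, counting neighbours within 1 kb or genes once, and averaging all regions of a gene in the list tests. Chosen after seeing the data were centring each comparison on the median of the 28171 regions at or above the median base mean, subtracting a running median over 50 bins of base mean, testing apicidin only over the regions tested for GSI, taking the covariance from the shared DMSO libraries out of the difference, matching RBPJ regions on width, and counting only the region of highest base mean of each gene. The procedure was tested on simulated fold changes with 200 changed among 56342 regions. The changed regions were drawn from those at or above the median base mean, with normal noise of the size of the deposited SEs. The counts that follow therefore do not describe weaker regions, nor the case of SEs that are too small. For apicidin against DMSO it recovered 56, 154 and 200 changed regions at log2 changes of 0.5, 1 and 2, with 3, 9 and 9 false calls. For the difference it recovered 9, 94 and 193 with 0 false calls at each size, and with the shared covariance taken out 50, 156 and 200 with 1, 4 and 10 false calls. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.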

Results

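H3K27ac was measured by ChIP-seq in Beko pre-T cells after 24 h of DMSO, apicidin or the gamma-secretase inhibitor DAPT (GSI), with 2 libraries per condition, and RBPJ binding was mapped in DMSO cells with 2 libraries. The authors' deposited table listed 56342 regions of H3K27ac on mm9 with a median width of 620 bp (quartiles 322 and 1457) and a median base mean of 61.3 (range 6.56 to 14330). Of these regions, 7889 covered a TSS and 48453 did not, and 1538 (2.73%) overlapped an RBPJ site. RBPJ-overlapping regions were strong and promoter-rich: their median base mean was 496 against 58.4 for the others, and 61.6% of them covered a TSS against 12.7%. The authors' fold changes are relative to DMSO throughout, and the depth of single libraries is unknown.

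The effect of blocking histone deacetylation on H3K27ac was addressed by apicidin against DMSO. Among regions at or above the median base mean, the largest increases in the authors' deposited table lay near Hs6st1 (log2 fold change 3.39 ± 0.40 SE, adjusted p = 1.03e-15), Rundc3a (2.97 ± 0.31, adjusted p = 5.06e-20), Sema6a (2.85 ± 0.22, adjusted p = 5.63e-34) and Ccr9 (2.73 ± 0.12, adjusted p = 2.92e-111), which encodes a chemokine receptor of thymocytes. All 10 regions assigned to Ccr9 rose, and so did 7 of 24 for Hs6st1, 2 of 2 for Rundc3a and 1 of 6 for Sema6a, by the calls in the authors' deposited table. The largest decreases there were at Ptpla (-2.37 ± 0.24, adjusted p = 5.21e-21), Rxra, a nuclear receptor gene (-2.17 ± 0.34, adjusted p = 3.37e-09), the stress-response gene Trib3 (-2.16 ± 0.25, adjusted p = 1.00e-15) and Dagla (-2.13 ± 0.17, adjusted p = 1.37e-32), again from the authors' deposited table. Across all regions the authors' deposited table called 13420 (23.8%), of which 5462 were higher and 7958 lower, with median log2 fold changes of 0.81 and -0.65. Among changes of at least 1 on the log2 scale the larger side turned, with 1944 higher and 1564 lower. The counts were normalised by the authors, so a change common to all regions may have been removed. Higher and lower are therefore relative to the other regions, here and below. At least 1 region rose for 2814 genes and fell for 5090, some genes having both. By the region of highest base mean of each gene, 1449 genes were higher and 4048 lower.

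Direction followed the strength of a region and its place, the latter to an extent that depended on how strength was matched. Regions covering a TSS were lower 3105 times and higher 632 times in the authors' deposited table, with a median log2 fold change of -0.24, whereas regions off a TSS were higher 4830 times and lower 4853 times, with a median of 0.06. The difference of the medians of promoter and distal regions, -0.29, shrank to -0.05 at matched signal density, with promoters lower in 7 of 15 bins. The median moved from 0.46 in the lowest decile of base mean to -0.15 in the highest, while over all regions it was 0.0040. For comparison, the GSI medians of the same deciles were 0.06 and 0.01. The split of calls therefore depends on where 0 is set: centring on the stronger regions, whose median was -0.10, gave 7149 higher and 5866 lower (54.9% higher, against 40.7% as deposited), and subtracting the trend over base mean gave 6506 higher and 5918 lower.

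**Figure D1:**
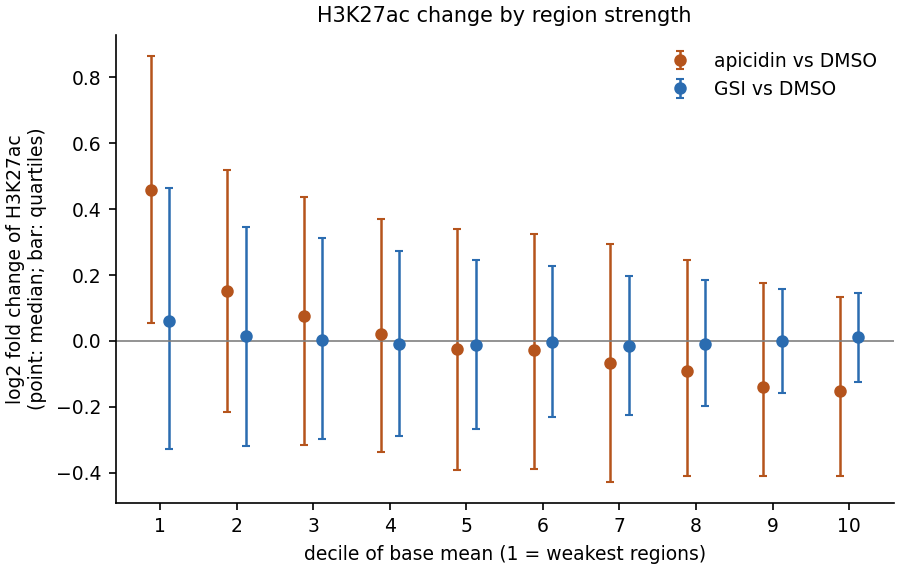
Median log2 fold change of H3K27ac (vertical axis, with quartiles as bars) against the decile of base mean (horizontal axis, 1 being the weakest regions), for apicidin and GSI against DMSO, from the authors' deposited table. Apicidin medians go from 0.46 in decile 1 to -0.15 in decile 10, and GSI medians from 0.06 to 0.01.

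Among the fixed lists, T-lineage genes rose more often than they fell with apicidin. Of 35 such genes 13 rose, 7 fell and 15 were not called, or 14 and 9 adjusted over the list alone. On centring 15 rose and 2 fell, and after subtracting the trend 15 and 1. By the values of the authors' deposited table, the transcription factor gene Tcf7 rose by 1.22 ± 0.07 (adjusted p = 8.47e-63, 11 of 13 regions higher) and the adhesion receptor gene Cd2 by 1.81 ± 0.11 (adjusted p = 1.52e-59, 8 of 17). Lef1, which encodes a relative of the Tcf7 product, rose in the authors' deposited table by 1.73 ± 0.13 (adjusted p = 2.30e-38, 8 of 65 higher and 1 lower) and Thy1 by 0.62 ± 0.05 (adjusted p = 5.40e-29, 5 of 14). The Lef1 region of highest base mean, which entered the list count, was not called (-0.02). The list median of 0.05 (0.15 on centring, 0.16 without the trend) stood at percentile 99.53 of matched random lists (permutation p = 0.0096), but not past adjustment over the 44 list tests (adjusted p = 0.130). Without passing adjustment either, 13 NF-kB and cytokine genes ranked high by their strongest regions (6 rose, 2 fell, 5 not called, or 7 and 2 adjusted over the list alone; percentile 99.27, adjusted p = 0.130), but at percentile 89.81 with all regions of a gene averaged, against 99.62 for the T-lineage genes. Within the authors' deposited table, Ifng, the interferon-gamma gene, rose by 1.14 ± 0.13 (3 of 6 regions) and Tnf by 0.82 ± 0.11 (1 of 2). Of 7 natural killer and innate lymphoid genes 2 rose and 5 were not called, or 3 higher adjusted over the list alone (percentile 99.31, adjusted p = 0.130, and percentile 95.84 averaged). Gzma, a granzyme gene, rose by 0.82 ± 0.07 (4 of 10 regions) in the authors' deposited table. The random lists were matched on base mean, not on covering a TSS or on regions per gene. At matched base mean, promoters differed from distal regions by -0.209 with apicidin. The 35 T-lineage genes had 790 regions, against 56342 for 12081 symbols in all. Whether place or region number accounts for the apicidin list ranks, here and below, was not tested.

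Several genes of the acetylation machinery were lower with apicidin. Of 13 histone acetyltransferase and bromodomain genes 9 fell and 4 were not called, or 10 lower adjusted over the list alone, with a list median of -0.42 (percentile 4.29, permutation p = 0.0860, adjusted p = 0.420). With all regions of a gene averaged the median was -0.0060 (percentile 79.10), so the list as a group did not pass. Per the authors' deposited table, the acetyltransferase genes Ep300 and Crebbp fell by 0.76 ± 0.07 (1 of 4 regions, adjusted p = 3.20e-22) and 0.85 ± 0.12 (1 of 1, adjusted p = 1.17e-10). The acetyl-lysine reader gene Brd2 fell in the authors' deposited table by 0.55 ± 0.07 (1 of 4, adjusted p = 1.69e-15). The HDAC/NCoR complex was mixed, with 2 of 25 genes higher, 6 lower and 17 not called (4 and 6 adjusted over the list alone), and its median of -0.07 became 0.03 on centring, with 6 genes higher and 5 lower. Its list ranked at percentile 90.46 by the strongest region of each gene, and at 99.92 (adjusted p = 0.0396) when all regions of a gene were averaged. In the authors' deposited table Hdac2 fell by 0.73 ± 0.10 (1 of 1 regions), while Tbl1xr1 rose by 0.69 ± 0.08 (12 of 43). Hdac3, the labelled target, had 1 region with a log2 fold change of 0.11 ± 0.14 (adjusted p = 0.651) for apicidin and 0.13 ± 0.15 (adjusted p = 0.660) for GSI in the authors' deposited table.

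Some proliferation genes and histone genes were lower with apicidin. Of 26 cell-cycle genes 2 rose, 11 fell and 13 were not called, or 2 and 14 adjusted over the list alone, and the list median of -0.21 lay at percentile 48.23 of matched lists. That median was -0.11 on centring, -0.06 without the trend, and 0.0020 with all regions of a gene averaged. Cdc20 fell by 0.89 ± 0.09, Cdk1 by 0.78 ± 0.09 and Mki67 by 0.69 ± 0.08 at the promoter of each (1 of 1, 1 of 1 and 1 of 5 regions) in the authors' deposited table. Of 17 cell-cycle inhibitors and p53 targets 3 rose, 8 fell and 6 were not called (3 and 10 adjusted over the list alone, percentile 12.11). By the values of the authors' deposited table, Cdkn2c fell by 0.81 ± 0.05 (1 of 1 regions) and Cdkn1a by 0.57 ± 0.10 (1 of 3), whereas the growth-arrest gene Gadd45g rose by 2.36 ± 0.17 (2 of 5). Among 8 replication-dependent histone genes 5 fell and 3 were not called (5 lower adjusted over the list alone, percentile 21.67). Of 7 histone variant genes 5 fell and 2 were not called (5 lower adjusted over the list alone, percentile 25.49), with 3 lower after subtracting the trend. Within the authors' deposited table, H2afz fell by 0.80 ± 0.09 (1 of 2 regions).

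GSI against DMSO asked which H3K27ac depends on gamma-secretase, and with it on Notch cleavage. Regions of many known Notch targets fell. Per the authors' deposited table, the RBPJ-overlapping region at the Hes1 promoter (chromosome 16, 30065308 to 30067169) fell by 1.24 ± 0.15 (adjusted p = 7.73e-14) and the Dtx1 promoter region (chromosome 5, 121154075 to 121166054) by 1.27 ± 0.08 (adjusted p = 2.90e-58). Ptcra, which encodes the pre-T cell receptor alpha chain, fell in the authors' deposited table by 1.01 ± 0.06 (adjusted p = 4.28e-60), and Il2ra (chromosome 2, 11538831 to 11551364, RBPJ-overlapping) by 0.96 ± 0.06 (adjusted p = 1.70e-46). Of 21 Notch/RBPJ target genes 12 fell, 8 were not called, 1 was untested and 0 rose by the calls of DESeq2 that the authors deposited, with 13 lower adjusted over the list alone and 0 higher at an unadjusted p under 0.05. The list median of -0.40 lay below all matched lists (permutation p = 0.0002, the smallest that 10000 draws give; adjusted p = 0.0088 over 44 tests).

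Decreases recurred over many regions of the same Notch targets. By the calls in the authors' deposited table, 8 of 9 tested Hey1 regions fell, 8 of 9 for Il2ra, 5 of 6 for Notch1, 4 of 5 for Notch3, 3 of 5 for Dtx1, 2 of 2 for both Hes1 and Heyl, 2 of 4 for Nrarp, and 1 of 1 for both Ptcra and Myc. In the authors' deposited table the smallest-p regions of Notch3, Hey1 and Notch1 fell by 0.93 ± 0.07, 0.88 ± 0.07 and 0.77 ± 0.05. Those of Heyl, Nrarp and Myc fell in the authors' deposited table by 0.52 ± 0.07, 0.43 ± 0.07 and 0.40 ± 0.06. Cdkn1a had a value of -0.20 ± 0.10 (adjusted p = 0.206) and the RBPJ-overlapping promoter region of Rbpj -0.11 ± 0.10 (adjusted p = 0.550) for GSI in the authors' deposited table. Of 20 Notch pathway and RBPJ cofactor genes 1 rose, 17 were not called and 2 were untested with GSI (1 higher adjusted over the list alone, percentile 29.69), and 2 rose, 6 fell and 12 were not called with apicidin (2 and 6 adjusted over the list alone, percentile 70.28).

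With apicidin, target genes went lower at some regions and higher at others. Of the 21 Notch/RBPJ targets 13 fell, 1 rose and 7 were not called with apicidin (15 and 1 adjusted over the list alone; 11 lower and 3 higher on centring and also without the trend), with a list median of -0.33 at percentile 6.04 (permutation p = 0.121, adjusted p = 0.532), and of -0.10 at percentile 46.11 when all regions of a gene were averaged. The smallest p among the listed genes was at Cd44, an adhesion receptor gene, which rose by 1.80 ± 0.16 (adjusted p = 2.83e-28) with apicidin and by 0.58 ± 0.17 (adjusted p = 0.0074) with GSI in the authors' deposited table. Of its 20 regions 4 rose and 1 fell with apicidin, the latter being its strongest (-0.39 ± 0.07), and of 7 tested with GSI 2 rose and 1 fell, per the authors' deposited table. By the values of the authors' deposited table, Hes1 fell by 0.61 ± 0.14 (1 of 3 regions), Heyl by 0.52 ± 0.07 (2 of 4), Hey1 by 0.71 ± 0.07 (15 of 21) and Nrarp by 0.72 ± 0.07 (3 of 8). Further decreases in the authors' deposited table were at Notch1, which fell by 0.30 ± 0.05 (2 of 14), Notch3 by 0.36 ± 0.07 (3 of 7), Ptcra by 0.49 ± 0.06 (1 of 1) and Myc by 0.26 ± 0.06 (1 of 2). For Il2ra, 2 of 16 regions fell, the smallest-p region by 0.36 ± 0.07, and 1 rose by 0.44 ± 0.12 in the authors' deposited table. Dtx1 had 1 of 11 regions lower, at -0.23 ± 0.07 (adjusted p = 0.0088) in the authors' deposited table, and that call was lost on centring. For Rbpj, 2 of 9 regions rose with apicidin, the smallest-p region by 2.70 ± 0.70 (adjusted p = 0.0010) at a base mean of only 18.9 in the authors' deposited table.

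**Figure D2:**
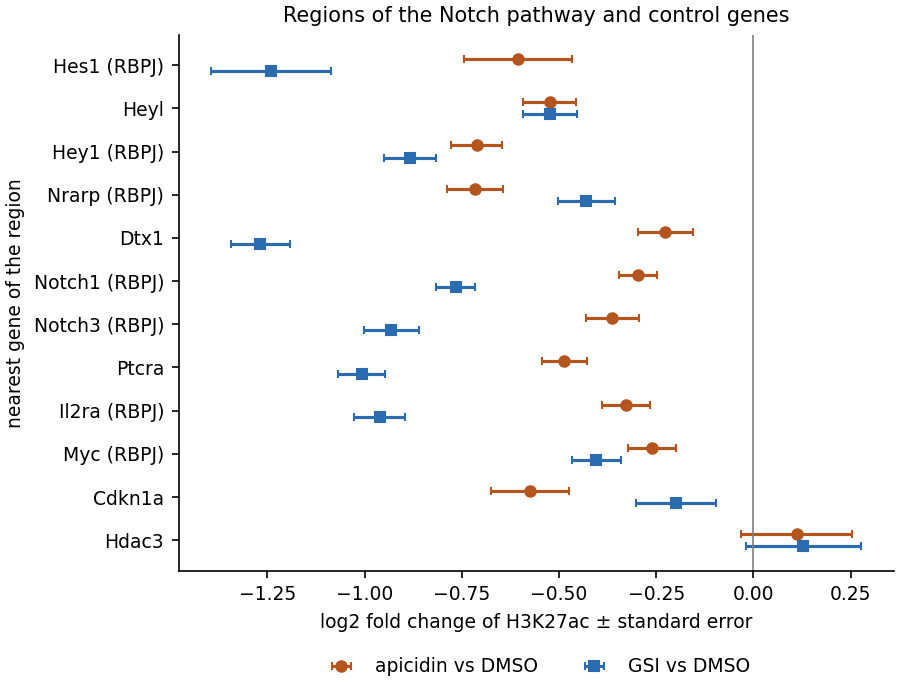
Log2 fold change of H3K27ac ± SE (horizontal axis) at the region with the smallest GSI p of each fixed gene except Rbpj, which is not shown (vertical axis), for apicidin and GSI against DMSO, from the authors' deposited table, with RBPJ-overlapping regions marked. Dtx1 lies at -1.27 for GSI and -0.23 for apicidin, Hes1 at -1.24 and -0.61, and Hdac3 at 0.13 and 0.11.

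Larger decreases with GSI lay outside these genes. Within the authors' deposited table, RBPJ-overlapping regions near Rapgef1 (chromosome 2, 29397918 to 29401391) and Gm266 (chromosome 12, 112707455 to 112715455) fell by 2.09 ± 0.10 (adjusted p = 1.12e-95) and 1.82 ± 0.07 (adjusted p = 1.25e-129). Regions near Gm5122, Exoc3l4 and Ptpro fell in the authors' deposited table by 1.64 ± 0.11, 1.62 ± 0.10 and 1.61 ± 0.13. The Exoc3l4 region (chromosome 12, 112664466 to 112670999) lies close to the Gm266 region, so these decreases may not be independent. At or above the median base mean of tested regions, the largest increases in the authors' deposited table were at Ccr9 (2.76 ± 0.12, adjusted p = 1.81e-110), the cytokine receptor gene Il21r (2.53 ± 0.18, adjusted p = 1.50e-41), Rhbdl3 (2.27 ± 0.15, adjusted p = 2.25e-46) and She (2.18 ± 0.16, adjusted p = 6.05e-39), with 5 of 5 tested Ccr9 regions higher. By the calls there, 9 of 28 tested Rapgef1 regions fell and 1 rose, 4 of 4 fell for Gm266, 1 of 4 for Gm5122, 1 of 1 for Exoc3l4 and 5 of 7 for Ptpro. For each of Il21r, Rhbdl3 and She, 1 of 1 rose. By the region of highest base mean of each gene, 816 genes were higher and 716 lower with GSI. GSI calls numbered 3553 of 25756 tested regions (13.8%) in the authors' deposited table, 1706 higher and 1847 lower, with medians of 0.49 and -0.56. Changes of at least 1 on the log2 scale numbered 137 higher and 164 lower among the regions tested for GSI. The GSI share is over stronger regions than the apicidin share given above. Among the same 25756 regions, 3991 were called higher and 6836 lower with apicidin.

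Replication-dependent histone genes moved up with GSI: of 8 genes 4 rose, 3 were not called and 1 was untested, or 5 higher adjusted over the list alone, with a list median of 0.29 at percentile 99.91 (permutation p = 0.0020, adjusted p = 0.0440). Per the authors' deposited table, Hist1h3c rose by 0.32 ± 0.05 (adjusted p = 1.68e-08), Hist1h1b by 0.31 ± 0.06 (adjusted p = 7.49e-06) and Hist1h4b by 0.27 ± 0.06 (adjusted p = 2.11e-04). These genes sit in clusters, so their regions are not independent, and with all regions of a gene averaged the list did not pass adjustment (percentile 99.52, adjusted p = 0.108). Of 35 T-lineage genes 5 rose, 9 fell, 20 were not called and 1 was untested with GSI (7 and 11 adjusted over the list alone, percentile 56.33). In the authors' deposited table the recombinase gene Rag1 fell by 1.12 ± 0.11 (adjusted p = 1.06e-22), and Cd2 rose by 1.14 ± 0.11 (adjusted p = 3.72e-22, 4 of 8 tested regions).

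The other lists gave few calls with GSI, and none of their medians passed adjustment over the 44 tests. With apicidin, 6 of 12 interferon response genes fell (6 adjusted over the list alone), and with GSI 1 fell (1). Of 16 cholesterol and lipid genes 2 rose and 7 fell with apicidin (3 and 8 adjusted over the list alone), with 4 lower on centring. With GSI the authors' DESeq2 calls and the list-alone count were both 0, against 3 higher and 2 lower at an unadjusted p under 0.05. For 20 ribosomal protein genes the counts were 1 higher and 6 lower with apicidin (1 and 7 adjusted over the list alone) and 1 lower with GSI (1). For 13 housekeeping genes they were 3 higher and 5 lower with apicidin (3 and 5 adjusted over the list alone) and 2 higher with GSI (2). Among 13 heat shock and unfolded protein genes 2 were higher and 4 lower with apicidin (2 and 4 adjusted over the list alone) and 2 higher with GSI (2), the latter lost when the trend was subtracted. Of 14 apoptosis genes 3 fell with apicidin (3 adjusted over the list alone), and 1 rose and 1 fell with GSI (2 and 1), the increase being lost when the trend was subtracted. Cell-cycle genes had 1 higher and 3 lower with GSI (1 and 3 adjusted over the list alone, percentile 1.83, adjusted p = 0.231), cell-cycle inhibitors and p53 targets 2 and 1 (6 and 1), histone variants 1 higher (1, lost when the trend was subtracted), and the HDAC/NCoR complex 1 and 3 (1 and 3). With GSI, the 13 acetyltransferase and bromodomain genes had 0 calls by the authors' DESeq2 and over the list alone, with 2 lower at an unadjusted p under 0.05. The 11 tested NF-kB and cytokine genes had 0 calls by the authors' DESeq2, with 1 higher adjusted over the list alone and 1 higher and 1 lower unadjusted.

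Markers of other cell types showed no common direction. With apicidin, 2 of 7 B-lineage genes fell (2 adjusted over the list alone, calls that centring removed), 1 of 6 myeloid genes rose and 1 fell (1 and 2), 1 of 7 erythroid and megakaryocyte genes rose and 2 fell (2 and 3). With apicidin, 2 of 7 neuronal genes also rose (2), and 2 of 9 fibroblast and epithelial genes rose and 3 fell (2 and 3). With GSI the erythroid and megakaryocyte genes had 1 higher and 2 lower (2 and 2 adjusted over the list alone), natural killer genes 1 higher (1), neuronal genes 1 higher of 4 tested (1), and fibroblast and epithelial genes 1 and 1 (1 and 1). The 6 B-lineage and 3 myeloid genes that were tested with GSI had 0 calls by the authors' DESeq2 and over the list alone, with 1 B-lineage and 0 myeloid genes lower at an unadjusted p under 0.05. By the values of the authors' deposited table, the erythroid regulator gene Gfi1b fell by 0.46 ± 0.12 with apicidin (3 of 10 regions) and, at a different region, by 0.68 ± 0.14 with GSI (2 of 6 tested). The neuronal splicing factor gene Rbfox3 rose in the authors' deposited table by 1.40 ± 0.19 (2 of 4) and 1.37 ± 0.19 (3 of 3 tested).

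RBPJ sites were examined to ask whether H3K27ac changed more often where RBPJ binds. With GSI, 154 of 1538 RBPJ-overlapping regions fell, among them regions of Hes1, Notch1, Notch3, Hey1 and Il2ra, against 104 in matched regions (central 95% 87 to 122, ratio 1.48, permutation p = 0.0002, the smallest possible, adjusted p = 0.0004 over 18 tests). Increases were rarer there, with 68 regions against 116 (97 to 135, permutation p = 0.0002, adjusted p = 0.0004). The excess of decreases was larger off TSS, with 99 of 591 regions against 61.5 (48 to 75, ratio 1.61, permutation p = 0.0002, adjusted p = 0.0004), than on TSS, with 55 of 947 against 42.4 (32 to 54, permutation p = 0.0452, adjusted p = 0.0626). Whether the excess differs between them was not tested. The matched sets were drawn region by region although neighbouring regions tend to move together. The intervals and permutation p-values of RBPJ regions can therefore be too narrow and too small. With apicidin, RBPJ-overlapping regions fell 567 times against 536 (503 to 569, ratio 1.06, permutation p = 0.0694, adjusted p = 0.0833) and rose 140 times against 209 (184 to 234, permutation p = 0.0002, adjusted p = 0.0004). On TSS, apicidin decreases equalled the matched regions (402 against 402, 375 to 430), and off TSS they exceeded them (165 against 134, 115 to 153, permutation p = 0.0032, adjusted p = 0.0058). With matching on width in place of base mean the apicidin excess over all RBPJ regions passed the threshold (ratio 1.19, permutation p = 0.0002), as did the GSI decreases on TSS (adjusted p = 0.0497), and with a log2 fold change of at least 1 required for apicidin it turned into a deficit (ratio 0.62, permutation p = 0.0166).

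**Figure D3:**
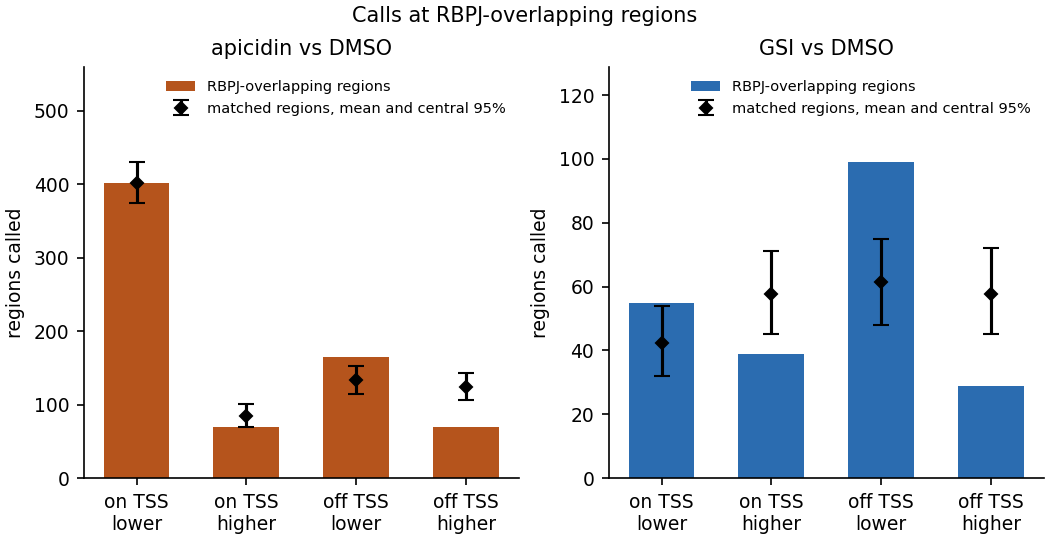
Number of RBPJ-overlapping regions called lower or higher (bars, vertical axis) on and off a TSS, for apicidin and GSI against DMSO, with the mean and central 95% of 10000 sets of regions matched on base mean and TSS (diamonds and whiskers), from calls in the authors' deposited table. Off TSS, 99 regions fell with GSI against 61.5 in matched sets.

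The treatments shared many regions. Ccr9, Il21r, Rhbdl3 and She rose with both, by 2.73 ± 0.12, 2.32 ± 0.18, 2.23 ± 0.15 and 2.09 ± 0.16 with apicidin in the authors' deposited table. Regions near Rapgef1, and near Gm266 and Exoc3l4, which lie close together, fell with both. With apicidin these regions fell in the authors' deposited table by 1.43 ± 0.09, 1.05 ± 0.07 and 1.03 ± 0.09. The strongest Rapgef1 region rose with both, and 3 of 56 Rapgef1 regions rose and 16 fell with apicidin. Of the 1847 regions lower with GSI, 1003 were also lower with apicidin, 721 not called and 123 higher. Of the 1706 regions higher with GSI, 989 were higher with apicidin, 546 not called and 171 lower. Independent lists among the 25756 regions tested in both would share 490 lower and 264 higher regions. They would hold 286 regions lower with GSI and higher with apicidin, and 453 higher with GSI and lower with apicidin. The covariance of both log2 fold changes across regions, which are not independent replicates, was 0.0808 against 0.0176 simulated (highest 0.0182), a difference of 0.0632. The correlation across regions was 0.476 against 0.501 simulated, and 63.8% of regions had the same sign against 66.7% simulated. The simulations split the noise evenly between treated and control libraries, which fixes these last measures, so neither can decide. Part or all of the excess over independent lists may come from the shared DMSO libraries. Of the 154 RBPJ-overlapping regions lower with GSI, 83 were also lower with apicidin, 52 were not called and 19 were higher.

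The treatments also parted at named regions. Within the authors' deposited table, the Lef1 region at chromosome 3, 130808623 to 130811580, rose by 1.73 ± 0.13 with apicidin and fell by 0.58 ± 0.15 with GSI, a difference of 2.31 ± 0.20 (adjusted p = 1.34e-27). Regions near Gm5122 and Ptpro likewise rose with apicidin, by 0.68 ± 0.10 and 0.56 ± 0.11, and fell with GSI in the authors' deposited table, with differences of 2.32 ± 0.15 (adjusted p = 1.63e-49) and 2.17 ± 0.17 (adjusted p = 3.45e-33). For Tcf7 the GSI value was -0.03 ± 0.08 in the authors' deposited table and the difference 1.25 ± 0.10 (adjusted p = 6.88e-30). The Notch targets fell further with GSI at Dtx1 (difference 1.04 ± 0.10, adjusted p = 4.55e-20), Il2ra (0.63 ± 0.09, adjusted p = 3.56e-10) and Notch3 (0.57 ± 0.10, adjusted p = 5.42e-07). So did Ptcra (0.52 ± 0.08, adjusted p = 5.42e-08), Notch1 (0.47 ± 0.07, adjusted p = 3.13e-09) and Hes1 (0.63 ± 0.21, adjusted p = 0.0295). At the smallest-p region of each, no difference was called for Heyl (-0.0010 ± 0.10, adjusted p = 1.00), Hey1 (0.17 ± 0.09, adjusted p = 0.340), Nrarp (-0.29 ± 0.10, adjusted p = 0.0584) or Myc (0.14 ± 0.09, adjusted p = 0.457). Another Hey1 region fell further with apicidin (difference -0.33 ± 0.11, adjusted p = 0.0378). In the opposite direction, the Hist1h3c region rose with GSI and fell by 0.45 ± 0.05 with apicidin in the authors' deposited table (difference -0.78 ± 0.07, adjusted p = 6.43e-23). The promoter of the mitotic cyclin gene Ccnb2 fell by 1.21 ± 0.11 with apicidin and rose by 0.36 ± 0.11 with GSI in the authors' deposited table (difference -1.56 ± 0.16, adjusted p = 1.16e-19). Of 13 Ccnb2 regions, however, 4 rose with apicidin and 2 fell. Over all regions the difference was called at 4853, with apicidin above GSI at 1698 and below at 3155. After centring these were 2367 and 2133 (52.6% above, against 35.0%).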

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

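In this part, centring, the subtracted trend, the shared covariance, width matching, the region of highest base mean per gene and the restriction to regions tested for GSI were chosen only after the results were seen. At adjusted p under 0.01, GSI gave 1103 higher and 1231 lower regions, the difference of apicidin and GSI 1072 above and 2077 below, 624 regions were lower in both comparisons and 139 called oppositely. At adjusted p under 0.1, 446 were called oppositely, and the apicidin decreases at RBPJ regions passed the threshold (ratio 1.065). With an absolute log2 fold change of at least 1 as well, apicidin gave 1944 higher and 1564 lower, GSI 137 and 164, the difference 454 and 546, with 38 lower in both, 106 higher in both and 1 called oppositely. On TSS apicidin then gave 42 higher and 172 lower, and the ratio at RBPJ regions reversed to 0.616. Bonferroni adjustment left 1515 and 2399 for apicidin, 394 and 551 for GSI, 370 and 730 for the difference, 229 lower in both, 236 higher in both, 23 called oppositely, and 227 higher and 1203 lower on TSS. Stricter thresholds lower counts by construction; the cause of the reversed ratio was not tested.

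Subtracting the trend over base mean turned the difference to 2559 above and 1866 below and left 1045 higher and 2026 lower regions on TSS for apicidin. Taking the shared covariance out gave 4324 above and 6729 below, which follows from its smaller SE. Width matching raised the ratio of apicidin decreases at RBPJ regions to 1.187, past the threshold; the cause was not tested. Counting each gene once per direction, so that a gene with regions of both directions counts in both, gave 2814 higher and 5090 lower for apicidin, 1221 higher and 1143 lower for GSI, the larger side changing, and 1100 above and 2643 below for the difference. Taking only the region of highest base mean per gene gave 1449 higher and 4048 lower for apicidin, 816 higher and 716 lower for GSI, the larger side changing as well, and 636 above for the difference. The median over all regions for apicidin became 0.1031 on centring and -0.0991 at or above the median base mean, where that of GSI was -0.0010. Averaging all regions of a gene took the HDAC/NCoR list with apicidin past the threshold (percentile 99.92) and the replication-dependent histones with GSI below it (99.52); the cause was not tested. Of the remaining results that answer a comparison, 150 kept direction and side of the threshold or stayed within the limits set for a count. Of the values for single regions and other results, 545 did so, 25 lost a call, 10 moved and 0 reversed.

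Alternatives that need values per library were not run, since the table used here holds none: other count models, normalisation by size factors or library totals, a low-count filter, fits on 2 groups, replicate blocks, leaving out each library, pseudocounts, a low-value filter, rescaled or quantile-scaled libraries and the inter-gene correlation of the list test. No paired analysis was possible because no values per library were used here and nothing in the labels pairs the libraries.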

Other observations

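The genes in this paragraph were chosen after their values were seen, for having many called regions. With apicidin, the authors' deposited table has 28 of 44 regions near Ntn1 lower, with a median log2 fold change of -0.99, and 13 of 17 near its neighbour Stx8, 24 of 35 near Jazf1, and 15 of 21 near Hey1 with 14 of 19 near its neighbour Mrps28. Increases gathered near the transcription factor genes Runx1 (21 of 65, with 1 lower), Ets1 (12 of 43) and Maf (13 of 24, with 1 lower), and near Slc9a9 (14 of 20, median 1.03), again in the authors' deposited table. Dad1, which adjoins the T cell receptor alpha locus, had 12 of 20 regions higher with apicidin and 7 of 9 tested higher with GSI in the authors' deposited table. Decreases with GSI gathered near Gm20740 (14 of 34 tested), I730028E13Rik (11 of 13, median -1.01) and Lef1 (10 of 24, with 1 higher) in the authors' deposited table.

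In the tests that follow, the resampling of windows and those of a constant offset, of chance selection of weak regions, of an X shift in the DMSO libraries, of a shift in the shared libraries and of RBPJ sites among shared decreases were chosen only after the results they measure were seen. With apicidin, strong and promoter regions fell and weak regions rose. A constant scaling offset moves all deciles alike, whereas the highest and lowest deciles of base mean differed by -0.611 (95% interval -0.630 to -0.585), which argues against it as the whole cause. Weaker enrichment over background in the apicidin libraries may contribute: promoters lay below distal regions by -0.293, by -0.209 (-0.224 to -0.193) at matched base mean, but by only -0.054 (-0.074 to -0.040) at matched signal density, lower in 7 of 15 bins, a size between what was set in advance for that explanation and against it. Chance selection of weak regions stays open too, because the libraries on which regions were called are not given in the sources used here, although the lowest decile was at 0.062 (0.047 to 0.079) with GSI against 0.459 with apicidin. The biological explanation, redistribution of acetylation by deacetylase inhibition, cannot be told apart from weaker enrichment in this design.

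With GSI, X-linked regions called were higher 42 times and lower 3 times among 469 tested (93.3% higher, 95% interval 81.7 to 98.6), among them regions near Bcor, Cd40lg and Flna, against 47.4% of autosomal calls. The X-linked median with GSI lay 0.093 (0.064 to 0.123) above the autosomes. A shift of the whole X chromosome by 0.093 is argued against as the whole cause. After its subtraction 27 calls were still higher and 10 lower (73.0%, exact interval 55.9 to 86.2, and 52.6 to 90.2 when whole windows of 1 Mb were resampled). Both intervals of that share hold the shift fixed, and larger shifts within its own interval were not tried. An X shift in the DMSO libraries would appear with apicidin as well. There 38.2% (27.4 to 47.4 by resampled windows) of X-linked calls were higher against 40.8% of autosomal ones, which lies within that interval. Among regions tested for GSI, the X-linked median with apicidin lay -0.099 (-0.197 to -0.010) from the autosomes. Over all 934 X-linked regions, however, the apicidin median was 0.048, against 0.0040 over all regions. Of the 42 regions higher with GSI, some also rose with apicidin, as near Cd40lg (2.01 ± 0.23). Others fell, as at Emd (-0.72 ± 0.11). An X shift in the DMSO libraries therefore stays open. A few X-linked domains may account for part of the pattern: the 3 fullest windows of 1 Mb held 16 of the 42 higher regions (38.1%), and the others were spread over the rest of 22 windows, which leaves this open. No biological explanation was tested.

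Both treatments changed many of the same regions in the same direction. A shift of the shared DMSO libraries stays open. The covariance of both log2 fold changes, 0.0808, exceeded the 0.0182 reached in simulations. It also exceeded the 0.0337 that would result if all noise lay in the shared libraries. In both comparisons 1992 regions were called the same way. The simulations had no changed regions, so their value of 0 was largely fixed in advance and cannot decide. The bounds on the covariance, moreover, rest on SEs that may hold technical spread alone. The correlation (0.476 against 0.501 simulated) and the share with the same sign (63.8% against 66.7%) cannot decide. The simulations split the noise evenly between treated and control libraries, which fixes both measures whatever the size of the noise. Loss of Notch-dependent acetylation at RBPJ sites could not be decided from the overlap. Of the RBPJ-overlapping regions lower with GSI, 53.9% were also lower with apicidin. Among regions lower with GSI without RBPJ, matched on base mean and TSS, the share was 53.6% (46.8 to 60.4, permutation p = 1.00). Those regions fell with GSI too and may also depend on Notch. Equal shares therefore show only that RBPJ overlap added no detected effect. That interval is wide, so a small added effect stays open. The shared changes have no tested explanation that accounts for them. Called neighbours within 10 kb moved in the same direction in 86.8% of 4443 pairs with apicidin and 97.1% of 762 pairs with GSI, against 51.9% (48.8 to 54.0) and 50.8% (45.1 to 56.2) when calls were permuted, so region counts overstate the number of independent changes.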
